A study of Mus musculus with 39 samples.

How the data were processed

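The 12 deposited tables held UMI counts per cell, per the labels, from 10x 3′ libraries that the authors had processed with Cell Ranger 2.1.0 against GRCm38. The filters the authors applied before deposit are not stated; the fewest genes in a deposited cell were 601. The values were checked to be whole numbers, and each of 129441 cells was assigned to 1 of 39 libraries by its column name. Genes carried 23308 symbols, 465 of those tested being models named MSTRG outside the reference annotation, and positions are from GENCODE M21 on GRCm38. Cells with over 20% mitochondrial UMIs (273) were removed; the minimum of 500 genes removed 0. Depth was 7.38 to 113.79 M UMIs per library (M, mega), 2017.6 M in all, with 1322 to 5755 cells. Barcodes showed that 10 libraries carry those of the V3 kit, 8 of which were labelled V2 (control 7 d replicate 3, Pten 7 d replicates 3 and 4, both Pten-CNTF libraries and Pten/Socs3-CNTF 7 d replicates 4 to 6); every uninjured, 2 d and 21 d library compared carried V2 barcodes.

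Cells were scaled to 10000 counts, log transformed and clustered on 2000 variable genes, 30 principal components and 15 neighbours by Leiden at resolution 1 (scanpy 1.11.5, leidenalg 0.10.2, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9). Clusters were named from markers: 32 were RGC-like (105001 cells), 10 were set aside because their top 10 genes held more markers of another class than of RGCs, and 1 could not be named. Only RGC-like cells were summed. In 9 of the 10 (19073 cells) this rested on 1 marker with all 9 RGC markers detected, so they are not shown to be other cells. A wider class, this stricter one and all cells were compared, and the stricter one was chosen after counts of called genes under each had been seen. Scrublet called 45 cells (0.035%), too few to count as working.

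The plan fixed before the data were examined took each library as a replicate. Libraries of a group were then found to come in near-identical sets: within sets they differed by 1.47 to 4.23 times counting noise in 16 pairs (1.14 to 1.35 when cells were shuffled between them), and by 12.68 to 170.93 times in the 24 other pairs of a group. Libraries of a set were summed, giving 21 sets in 12 groups, and the sets became the main unit, a departure from the plan made after the counts under both units had been seen. The limit of 5 that separates them was also set after the values were seen, and each library as its own replicate was kept as an alternative. In 5 groups (control uninjured and at 2 d, Pten/Socs3-CNTF 2 d, Pten-CNTF 7 d and Pten no-AAV 2 d) there was 1 set, assumed to vary like the others; the comparisons of control 2 d with uninjured and of Pten/Socs3-CNTF with control at 2 d rest on 1 set against 1. Library numbers did not pair across groups: profiles with the same number correlated at 0.035 on average against -0.012 for others, and 13 of 34 libraries matched their own number best.

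Genes were tested in 1 edgeR 4.0.16 quasi-likelihood fit (R 4.3.3) with TMM scaling, after filterByExpr by group (minimum count 10, total 15), which left 21521 genes; the biological coefficient of variation was 0.308 and the residual degrees of freedom 9. Genes at a Benjamini-Hochberg adjusted p under 0.05 were called, in 15 comparisons of 2 groups and 2 contrasts of responses. The alternatives were DESeq2 1.42.0, median-ratio size factors, no count filter, at least 1200 genes per cell, all cells, only the groups compared, a replicate block, each library or set left out, and the V3-kit libraries added to the uninjured Pten group. Those added later were the barcode series as a term, V2 barcodes alone, each library as its own replicate, the fit without the 2 shallow Pten libraries (Pten 2 d replicate 3 and uninjured replicate 2), that with the 9 clusters set aside for 1 marker and that without the 5% of cells with the highest doublet scores. Changing the scaling moved the median log2 fold change of the Pten difference of responses most, by -0.069.

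Gene lists fixed before the data were examined (20 lists and markers of 12 other cell types, as named in the report) were tested by camera (limma 3.58.1) with a preset correlation of 0.01 and with an estimated one, adjusted over the 32 lists. The rule for naming genes took, per comparison, the 10 higher and 10 lower genes of smallest p among those called with a log2 fold change of at least 1 in size and each library of one group beyond each of the other, without predicted genes, Riken clones, mitochondrial and ribosomal genes, and up to 4 genes per list by size of change. It gave 615 entries of 286 genes; the text takes its examples from them, and genes with at most 3 UMIs in a group are given no fold. Egr2 and mt-Co1 (Pten 7 d over uninjured) and A2m (Pten/Socs3-CNTF over control at 7 d) entered by their list without that separation. Overlaps were tested by Fisher's exact test between comparisons that share no library; genes are not independent, so these p values are too small.

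The fit was tested on simulated data with known changes. Of genes changed 4-fold edgeR recovered 71.9% in Pten/Socs3-CNTF over control at 7 d, 59.6% in Pten over control at 7 d, 26.5% in control 7 d over uninjured, 0% in Pten/Socs3-CNTF over control at 2 d and 3 to 6.2% in the differences of responses, with 0 to 11 false calls, and DESeq2 made 0 to 54. Left out of the fit were 5 libraries: the uninjured ones without AAV, alone in their groups; the V3-kit pair, labelled AAV2-Cre but placed in a table named for CNTF; and 1 whose title says crush and whose label says no crush.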

Results

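Single cells from the retinas of mice aged 6 to 8 weeks were sorted on CD90 and on a yellow fluorescent reporter driven by Thy1, which enriches retinal ganglion cells (RGCs), the neurons whose axons form the optic nerve, and were counted as UMIs (unique molecular identifiers, 1 per captured transcript). The title of uninjured Pten replicate 2 names CD45 beside CD90. Crushing the optic nerve cuts these axons, and most RGCs then die. Pten and Socs3 restrain growth and cytokine signalling, and ciliary neurotrophic factor (CNTF) activates the latter, so that losing the genes and adding the factor is known to increase survival and axon regrowth. The deposit held 129441 cells in 39 libraries, of which 34 libraries in 12 groups were compared. Control mice carried the reporter and received an adeno-associated virus (AAV) with Cre, and the Pten group carried floxed Pten and received the same virus. The Pten-CNTF and Pten/Socs3-CNTF groups also received a virus with CNTF, the last carrying floxed Socs3 as well. Mouse line and deletion changed together in every comparison with controls, so no such comparison separates them. Within 5 of the groups all libraries were nearly identical, so that near-identical libraries were summed and 21 sets, not libraries, were counted as replicates.

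Library depth ranged from 7.38 to 113.79 M UMIs (M, mega), and the median per cell from 3284 to 27774. The control libraries held 40.43 and 32.43 M UMIs uninjured (1 set), 35.99, 37.61 and 31.15 at 2 d after crush (1 set) and 39.84, 50.58 and 74.02 at 7 d (2 sets). Pten libraries held 45.87 and 7.38 M uninjured (2 sets), 11.84, 55.72 and 59.72 at 2 d (replicates 3 to 5, 2 sets) and 30.85, 39.59, 59.59 and 59.88 at 7 d (3 sets). The Pten-CNTF libraries at 7 d held 94.3 and 59.18 M (1 set). Pten/Socs3-CNTF libraries held 50.29 and 19.57 M uninjured (2 sets), 44.68 and 54.16 at 2 d (1 set), 60.76, 42.11, 53.25, 83.92, 86.56 and 69.63 at 7 d (3 sets) and 59.32, 45.0 and 62.4 at 21 d (2 sets). Pten mice without AAV at 2 d gave 52.15 and 50.43 M (replicates 2 and 3, 1 set). Outside the comparisons lay uninjured libraries without AAV of the Pten line (23.79 M) and of the Pten/Socs3 line (48.69), a pair of uninjured Pten libraries made with the V3 kit (113.79 and 92.4) and 1 library with conflicting labels (38.72).

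Cells with the profile of RGCs made up 81.29% of the 129168 cells kept, in 32 of 43 clusters, and all comparisons below were made on them. Another 10 clusters were set aside because their top 10 genes held more markers of another class (Müller glia, horizontal or amacrine cells, astrocytes, microglia) than of RGCs. In 9 of them, with 19073 cells, this was 1 marker, while all 9 RGC markers were detected, so they are not shown to be other cells. The share set aside was 28.8% of uninjured control cells and 9.26% ± 5.64 at 7 d (SD, n = 2 sets). RGC-like cells were 71.19% of uninjured control cells, 85.78% at 2 d and 90.03% ± 4.66 at 7 d (SD, n = 2 sets). In Pten mice they were 73.17% ± 3.69 uninjured (n = 2), 68.0% ± 27.11 at 2 d (n = 2) and 73.08% ± 10.97 at 7 d (n = 3), and in Pten-CNTF mice 86.93% (n = 1). In Pten/Socs3-CNTF mice they were 79.58% ± 0.09 uninjured (n = 2), 91.83% at 2 d (n = 1), 85.24% ± 5.08 at 7 d (n = 3) and 86.71% ± 0.91 at 21 d (n = 2). A sorted fraction cannot give the number of cells that survived, so these shares were not tested.

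The targets of the manipulation came first. Pten encodes a phosphatase that limits growth signalling, and Socs3 an inhibitor of cytokine receptors that cytokines themselves induce. Tags at the 3′ end of a transcript can lie outside the part that Cre removes, so levels of neither gene measure the deletion. Pten (GRCm38 chromosome 19, 32757497 to 32826160) stood at 66.3 and 94.4 CPM (counts scaled to the library total, per 1 M) in the uninjured Pten libraries with Cre, against 138.1 in that line without AAV and 146.2 and 130.1 in uninjured controls. At 2 d it was 74.5 to 80.4 CPM with Cre and 106.2 and 108.7 without AAV in the Pten line, and 80.3 to 91 in controls. At 7 d it followed the barcode series: 55 and 58.9 CPM in V2 control libraries and 122.5 in the V3 one, 34.4 and 66.1 in V2 Pten libraries and 132.8 and 145.2 in V3 ones. Socs3 (chromosome 11, 117966079 to 117970047) was at 1.4 and 1.6 CPM in uninjured controls, at 1.3 in uninjured mice of the Pten/Socs3 line without AAV, and at 14.7 and 40.5 in uninjured Pten/Socs3-CNTF libraries. It reached 81.3 and 88.1 CPM in Pten-CNTF libraries at 7 d, 39.5 to 72.9 in Pten/Socs3-CNTF ones, and 3.4 in both V2 control libraries against 64.9 in the V3 one. Cntf was not listed in the tables, so expression of the factor could not be measured. None of these levels was among the genes chosen by the naming rule.

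**Figure D1:**
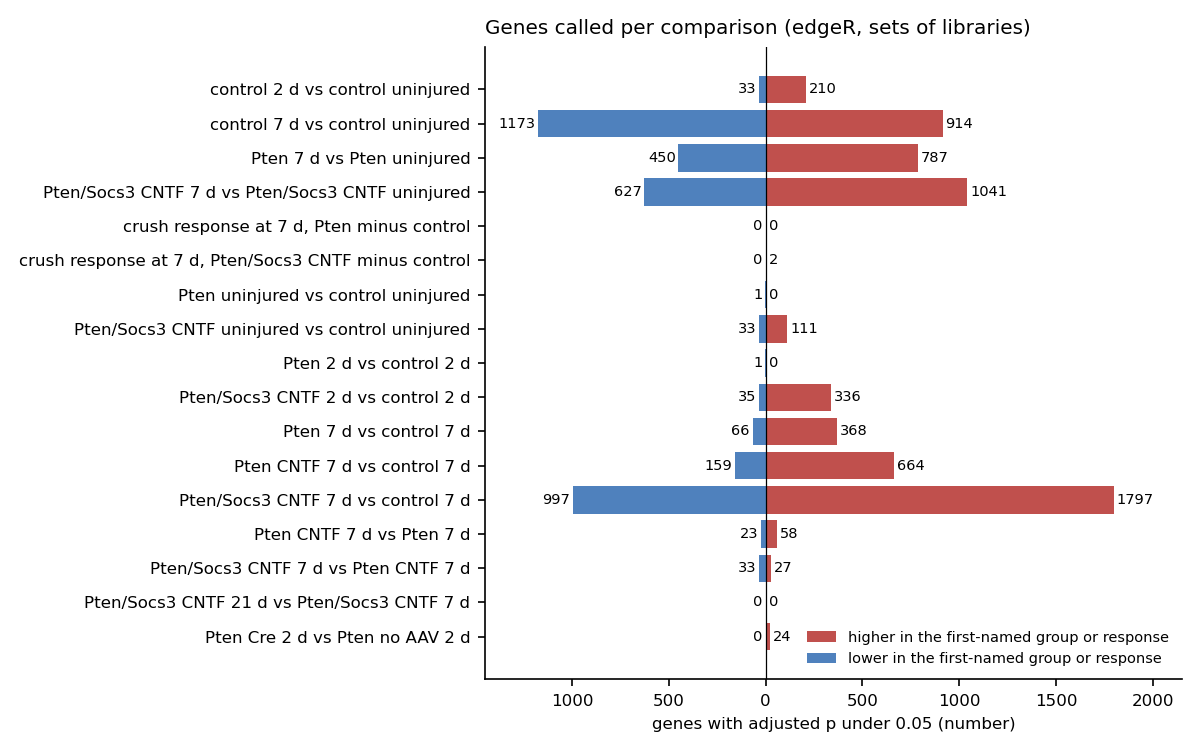
Bars give the number of genes called higher (right) and lower (left) in each of the 17 comparisons by edgeR at an adjusted p under 0.05, over 21521 genes in RGC-like cells. The counts run from 0 between 21 d and 7 d in Pten/Socs3-CNTF mice to 1797 higher and 997 lower between these mice and controls at 7 d.

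In every comparison values are log2 fold changes of the first group over the second with their standard error (SE) from edgeR, p values were adjusted over all genes tested, and n counts sets. For every gene given with a value below, each library of one group lay beyond each library of the other, apart from the contrasts of responses, where this was not assessed. A group of 1 set was assumed to vary like the other groups. Gene lists were fixed before the data were examined and tested against all other genes by limma's camera.

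The early response of RGCs to axon injury was read from controls at 2 d against uninjured controls (n = 1 and 1). Genes of the integrated stress response led it: Atf3, a transcription factor switched on by axon damage, Atf5 and Ddit3, which drive the response to misfolded protein and amino acid shortage, and Phgdh and Psph, which make serine. Sprr1a and Ecel1, found in many injured neurons, rose with them, as did the pro-death genes Hrk and Bcl2l11 and the macrophage elastase gene Mmp12. Lower were genes of lipid supply, among them Dhcr24, which completes cholesterol synthesis, Ldlr, which takes cholesterol up, and Sptssb, a subunit of the enzyme that starts sphingolipid synthesis, together with the nicotinic receptor gene Chrna6 of RGCs. edgeR called 210 genes higher and 33 lower . The log2 fold changes were 5.95 ± 0.83 for Atf3 (adjusted p = 0.00268), 4.60 ± 0.45 for Atf5 (adjusted p = 0.000607), 7.04 ± 0.95 for Sprr1a (adjusted p = 0.00219) and 5.15 ± 0.69 for Hrk (adjusted p = 0.00207). Lower values were -3.34 ± 0.42 for Sptssb (adjusted p = 0.00203), -2.43 ± 0.41 for Dhcr24 (adjusted p = 0.00904) and -2.62 ± 0.47 for Chrna6 (adjusted p = 0.0123). Atf3 lies on chromosome 1 (191170296 to 191218039). Of the 26 stress response genes, 16 were called higher, 0 lower and 10 neither (22 and 0 adjusted over the list alone); the median was 3.19 (adjusted p = 1.68e-53, and adjusted p = 0.00433 with an estimated correlation). Among 30 regeneration genes 6 were higher, 0 lower and 24 not called (12 and 0 adjusted over the list alone), at a median of 1.46 (1.41 with genes at 0 set to their bound) (adjusted p = 9.32e-14, and adjusted p = 0.0206 with an estimated correlation). The test called 0 of 24 cholesterol genes higher and 3 lower, leaving 21 (0 and 16 adjusted over the list alone), with a median of -1.45 (adjusted p = 3.34e-16, and adjusted p = 0.0292 with an estimated correlation). For the cell death genes, 4 of 24 were higher, 0 lower and 20 not called (5 and 0 adjusted over the list alone), and the list's median was 0.75 (adjusted p = 5.69e-07, and adjusted p = 0.0297 with an estimated correlation). Of the 21 neuropeptide genes, 2 were called higher, 0 lower and 19 neither (8 and 0 adjusted over the list alone); the median was 1.01 (1.31 with genes at 0 set to their bound) (adjusted p = 0.000323, and adjusted p = 0.0206 with an estimated correlation). Each group was 1 set, so leaving out a library removed no replicate and tells nothing of stability. DESeq2 called 437 genes higher and 210 lower, and edgeR with the barcode series as a term 447 and 224.

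Whether the injury response lasted was asked at 7 d, with controls against uninjured controls (n = 2 and 1). Called higher were Atf3, Atf5, Ecel1, Sema3c, a secreted guidance cue, Casp3, the protease that executes cell death, and Hspa5, the chaperone of the endoplasmic reticulum. Genes that RGCs need to signal fell, including the nicotinic receptor subunits Chrna6 and Chrnb3, the calcium sensor Hpca, the synaptic vesicle genes Vamp1 and Sv2b and parvalbumin (Pvalb). Cholesterol genes stayed low, and Aldoc, a glycolytic enzyme, was lower too. edgeR called 914 genes higher and 1173 lower. Rises were 6.82 ± 0.57 for Sema3c (adjusted p = 3e-05), 7.55 ± 0.78 for Ecel1 (adjusted p = 0.00012), 6.82 ± 0.85 for Atf3 (adjusted p = 0.000357) and 3.40 ± 0.34 for Casp3 (adjusted p = 9.93e-05), and falls were -4.94 ± 0.34 for Sptssb (adjusted p = 7.93e-06), -4.73 ± 0.39 for Chrna6 (adjusted p = 2.74e-05), -4.33 ± 0.45 for Hpca (adjusted p = 0.00012) and -3.50 ± 0.49 for Pvalb (adjusted p = 0.000723). The test called 3 of 17 endoplasmic reticulum stress genes higher and 0 lower, leaving 14 (6 and 0 adjusted over the list alone), with a median of 0.78 (adjusted p = 1.85e-05, and adjusted p = 0.0114 with an estimated correlation). For the excitability genes, 0 of 35 were higher, 14 lower and 21 not called (0 and 19 adjusted over the list alone), and the list's median was -1.10 (adjusted p = 1.58e-11, and adjusted p = 0.219 with an estimated correlation). Of the 33 interferon and antigen presentation genes, 11 were called higher, 0 lower and 22 neither (20 and 0 adjusted over the list alone); the median was 2.34 (adjusted p = 1.81e-11, and adjusted p = 0.281 with an estimated correlation). Among 22 glycolysis genes 2 were higher, 3 lower and 17 not called (2 and 9 adjusted over the list alone), at a median of -0.71 (adjusted p = 0.00472, and adjusted p = 0.446 with an estimated correlation). Called were 0 of 9 genes of direction-selective RGCs higher and 4 lower, leaving 5 (1 and 5 adjusted over the list alone), with a median of -0.85 (adjusted p = 0.0163, and adjusted p = 0.347 with an estimated correlation). The stress, regeneration, cholesterol, cell death and neuropeptide lists were again called with either correlation (adjusted p = 1.18e-29, 2.43e-16, 4.48e-13, 4.17e-07 and 0.000126). Calls held for 62 of the 76 genes named by the rule whichever library was left out, and the count stayed within 1.5 times. With DESeq2 the counts were 1384 genes higher and 1364 lower, and with the barcode series as a term in edgeR they were 1550 and 2102.

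The response to crush in the Pten group was taken at 7 d against the uninjured group (n = 3 and 2). It shared the injury genes of controls: Ecel1, Sprr1a, Nts, which encodes neurotensin, Mmp12, Hrk and Casp3 were higher, and Sptssb, Stard4, Ldlr and Dhcr24 lower. Interferon-stimulated genes, such as the guanylate-binding protein gene Gbp7, and Stat1, which carries interferon signals to the nucleus, were higher than before crush. Adcyap1, a neuropeptide of melanopsin RGCs, also rose. edgeR called 787 genes higher and 450 lower. Values were 10.18 ± 0.66 for Ecel1 (adjusted p = 2.23e-06), 11.75 ± 0.88 for Sprr1a (adjusted p = 3.86e-06), 5.38 ± 0.75 for Gbp7 (adjusted p = 0.000738) and 3.15 ± 0.39 for Adcyap1 (adjusted p = 3e-04), and -3.56 ± 0.26 for Sptssb (adjusted p = 3.17e-06), -1.74 ± 0.23 for Ldlr (adjusted p = 0.000528) and -1.78 ± 0.25 for Dhcr24 (adjusted p = 0.000761). For the interferon-stimulated genes, 27 of 33 were higher, 0 lower and 6 not called (30 and 0 adjusted over the list alone), and the list's median was 4.05 (adjusted p = 2.51e-45, and adjusted p = 0.0245 with an estimated correlation). Of the 30 regeneration genes, 16 were called higher, 0 lower and 14 neither (20 and 0 adjusted over the list alone); the median was 1.85 (1.78 with genes at 0 set to their bound) (adjusted p = 3.31e-34, and adjusted p = 0.00094 with an estimated correlation). Among 82 cytosolic ribosome genes 1 was higher, 0 lower and 81 not called (1 and 0 adjusted over the list alone), at a median of 0.67 (adjusted p = 9.65e-11, and adjusted p = 0.411 with an estimated correlation). The stress, endoplasmic reticulum, cholesterol, cell death and neuropeptide lists were called with either correlation (adjusted p = 2.4e-20, 0.000848, 9.52e-15, 2e-09 and 1.85e-14). With the preset correlation alone, markers were lower for bipolar cells and Müller glia. The count was 771 without Pten uninjured replicate 1, 780 without Pten uninjured replicate 2 and 807 without Pten 7 d replicate 2, and 37 of the 69 genes named by the rule held their call whichever library was left out. The counts were 1074 genes higher and 881 lower with DESeq2 and 1380 and 1274 in edgeR with the barcode series as a term.

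In Pten/Socs3-CNTF mice crush was followed at 7 d against uninjured ones (n = 3 and 2). Sex differed too, with Xist at 157.1 to 395.5 CPM against 0.0 and 0.2. Among the genes that rose were Emp3, a membrane protein, Procr, the protein C receptor, Flnc, a filamin that binds actin, Ecel1, Sprr1a and Atf3. The tubulin gene Tubb6, common in growing axons, was higher, and the inhibitor of metalloproteinases Timp1 with it. Chrna6, Pvalb, Sptssb and the mitochondrial subunit Cox6b2 were lower. edgeR called 1041 genes higher and 627 lower. Values were 4.56 ± 0.34 for Emp3 (adjusted p = 1.82e-05), 5.22 ± 0.50 for Ecel1 (adjusted p = 5.84e-05), 3.59 ± 0.51 for Tubb6 (adjusted p = 0.000959) and 4.51 ± 0.60 for Timp1 (adjusted p = 0.000595), and -3.15 ± 0.25 for Sptssb (adjusted p = 2.52e-05), -2.56 ± 0.29 for Chrna6 (adjusted p = 0.000188) and -2.40 ± 0.37 for Pvalb (adjusted p = 0.00154). The test called 19 of 30 regeneration genes higher and 0 lower, leaving 11 (21 and 0 adjusted over the list alone), with a median of 2.03 (adjusted p = 1.47e-27, and adjusted p = 0.00469 with an estimated correlation). For the stress response genes, 11 of 26 were higher, 0 lower and 15 not called (19 and 0 adjusted over the list alone), and the list's median was 1.30 (adjusted p = 1.02e-15, and adjusted p = 0.0627 with an estimated correlation). Of the 30 cytoskeleton genes, 7 were called higher, 0 lower and 23 neither (9 and 0 adjusted over the list alone); the median was 0.60 (adjusted p = 1.23e-05, and adjusted p = 0.143 with an estimated correlation). Markers of other cells, called with the preset correlation alone, were higher for rods, microglia and T cells. The count was 287 without uninjured replicate 1, 485 without uninjured replicate 2, 853 without 7 d replicate 3 and 896 without 7 d replicates 1 and 2. Of the 71 genes named by the rule 34 kept their call whichever library was left out. DESeq2 called 1362 genes higher and 953 lower, and edgeR with the barcode series as a term 1732 and 1465.

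The responses shared more genes than chance gives. Each set V3 and V2 libraries against V2 ones alone, so barcode series may add to this. Of the genes higher at 7 d in controls, 508 were also higher in Pten/Socs3-CNTF mice where 44.2 would be shared by chance, and 432 against 34.2 were lower in both, while 4 went opposite ways (Fisher's exact test, p at most 1e-300 in each direction). With Pten mice the shared genes were 544 against 33.4 higher (Fisher's exact test, p at most 1e-300) and 306 against 24.5 lower (p = 6.19e-287).

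Whether the deletions changed the response to crush itself was tested as a difference of differences at 7 d: the response of Pten mice (n = 3 and 2) or of Pten/Socs3-CNTF mice (n = 3 and 2) minus that of controls (n = 2 and 1). Stress response genes lay lower and RGC identity genes higher in both differences, in the direction of a smaller response, but the lists were called with the preset correlation alone. In the Pten/Socs3-CNTF difference Xist, which silences an X chromosome in females, and Abi3bp, a matrix-binding protein, were called. edgeR called 0 genes for Pten mice (1345 at an unadjusted p under 0.05), DESeq2 25 higher and 16 lower, and edgeR with the barcode series as a term 3 higher. For Pten/Socs3-CNTF mice edgeR called 2 higher and 0 lower (1441 at an unadjusted p under 0.05), DESeq2 105 and 68, and edgeR with the barcode series as a term 49 and 36. The value was 3.88 ± 0.55 for Abi3bp (adjusted p = 0.0466), with an adjusted p up to 0.333 when libraries were left out, and its call ended with the clusters of 1 other marker included. Xist stood at 0.0 and 0.2 CPM in the uninjured Pten/Socs3-CNTF sets, so no fold is given. Among 26 stress response genes in the Pten difference 0 were higher, 0 lower and 26 not called (0 and 13 adjusted over the list alone), at a median of -1.41 (adjusted p = 1.16e-22, and adjusted p = 0.0798 with an estimated correlation). Called were 0 of 26 stress response genes in the Pten/Socs3-CNTF difference higher and 0 lower, leaving 26 (0 and 14 adjusted over the list alone), with a median of -1.68 (adjusted p = 7.46e-25, and adjusted p = 0.0506 with an estimated correlation). For the RGC identity genes in the Pten difference, 0 of 25 were higher, 0 lower and 25 not called (1 and 0 adjusted over the list alone), and the list's median was 0.72 (adjusted p = 5.42e-08, and adjusted p = 0.247 with an estimated correlation). In the Pten/Socs3-CNTF difference the RGC identity list had a median of 0.76 (adjusted p = 7.51e-06, and adjusted p = 0.306 with an estimated correlation). With the preset correlation alone, markers in the Pten difference were higher for amacrine cells and lower for rods and Müller glia. In the Pten/Socs3-CNTF one they were higher for microglia, Müller glia and T cells. The Pten count was 1 without Pten 7 d replicate 2 and 57 without Pten uninjured replicate 1. The Pten/Socs3-CNTF count was 0 without Pten/Socs3-CNTF uninjured replicate 1 or 2, control 7 d replicate 3 or control 7 d replicates 1 and 2. It was 1 without Pten/Socs3-CNTF 7 d replicate 3, replicate 4 or replicates 1 and 2, or control 7 d replicate 2. Without Pten/Socs3-CNTF 7 d replicates 4 to 6 it was 13.

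The effect of the Pten deletion on uninjured RGCs was asked against uninjured controls (n = 2 and 1). No known gene was called. The 1 gene called lower was MSTRG.13167, a transcript model outside the reference annotation, which was at 0.2 to 5.7 CPM in all 20 sets of the floxed lines, with or without AAV, and at 111.6 to 357.7 in controls. Markers of Müller glia and of the early response to dissociation stood higher as lists with the preset correlation alone, through the shallow Pten replicate 2 (summed CPM 1737.8 and 7607.7, against 411.0 and 2979.2 in replicate 1 and 336.7 and 3235.6 in controls). edgeR called 0 genes higher and 1 lower, with 923 genes at an unadjusted p under 0.05. DESeq2 called 10 higher and 8 lower, and edgeR with the barcode series as a term 1 and 3. MSTRG.13167 had a log2 fold change of -6.83 ± 0.89 (adjusted p = 0.0394, and up to 0.245 without Pten uninjured replicate 2). Of the 10 Müller glia markers, 0 were called higher, 0 lower and 10 neither (6 and 0 adjusted over the list alone); the median was 3.99 (adjusted p = 4.07e-07, and adjusted p = 0.657 with an estimated correlation). Among 19 early response genes 0 were higher, 0 lower and 19 not called (1 and 0 adjusted over the list alone), at a median of 1.35 (adjusted p = 2.91e-07, and adjusted p = 0.657 with an estimated correlation). The count was 0 without Pten uninjured replicate 2 and 64 without Pten uninjured replicate 1, and 0 with the clusters of 1 other marker included.

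Before any crush, Pten/Socs3-CNTF RGCs differed from control RGCs in cytokine and interferon genes (n = 2 and 1). Serpina3n, a protease inhibitor induced through STAT3, was higher, as were Bdnf, which encodes a survival factor for neurons, Cd24a, a surface protein of growing neurites, Arpc1b, a subunit of the complex that branches actin, and the cadherin Cdhr1. Stmn1, which frees tubulin for remodelling, was far lower. Interferon-stimulated genes, read as a list, were higher. Xist stood at 0.0 and 0.2 CPM and the Y-linked Ddx3y at 35.2 and 44.6, against 1041.1 and 3.4 in controls, so the sex of the mice differed too. edgeR called 111 genes higher and 33 lower. Values were 5.50 ± 0.78 for Serpina3n (adjusted p = 0.00616), 3.09 ± 0.41 for Bdnf (adjusted p = 0.00328), 4.46 ± 0.57 for Cd24a (adjusted p = 0.00295) and 3.65 ± 0.40 for Cdhr1 (adjusted p = 0.000883), and -6.19 ± 0.49 for Stmn1 (adjusted p = 7.14e-05). Stmn1 (chromosome 4, 134468320 to 134473843) was at 17.8 to 171.1 CPM in the 8 sets of this group at all times, at 916.8 to 1669.0 in control sets and at 337.6 in uninjured mice of the same line without AAV. The test called 12 of 33 interferon-stimulated genes higher and 0 lower, leaving 21 (30 and 0 adjusted over the list alone), with a median of 3.46 (adjusted p = 1.22e-57, and adjusted p = 0.0137 with an estimated correlation). The test called 3 of 23 JAK/STAT targets higher and 0 lower, leaving 20 (9 and 0 adjusted over the list alone), with a median of 1.63 (adjusted p = 9.39e-17, and adjusted p = 0.0137 with an estimated correlation). Of the 21 neuropeptide genes, 0 were called higher, 0 lower and 21 neither (7 and 1 adjusted over the list alone); the median was 1.19 (1.36 with genes at 0 set to their bound) (adjusted p = 0.000127, and adjusted p = 0.0137 with an estimated correlation). Among 20 mitochondrial transcripts 0 were higher, 0 lower and 20 not called (0 and 0 adjusted over the list alone), at a median of -0.92 (adjusted p = 0.00168, and adjusted p = 0.368 with an estimated correlation). Markers of other cells, called with the preset correlation alone, were lower for bipolar cells, rods and microglia. The count was 27 without Pten/Socs3-CNTF uninjured replicate 1 and 43 without Pten/Socs3-CNTF uninjured replicate 2, and 13 of the 31 genes named by the rule kept their call whichever library was left out. With DESeq2 the counts were 324 genes higher and 68 lower, and with the barcode series as a term in edgeR they were 220 and 65.

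At 2 d after crush the Pten group was set against controls (n = 2 and 1). Interferon-stimulated genes were higher as a list in Pten mice. Microglia markers, not called as a list (median 1.33, adjusted p = 0.11), stood at 189.5 CPM in Pten replicate 3, 61.7 in the other Pten set and 77.6 in controls. No gene of the reference annotation was called by itself. edgeR called 0 genes higher and 1 lower, MSTRG.13167 at -6.78 ± 0.88 (adjusted p = 0.0371, and up to 0.413 with Pten 2 d replicates left out). Genes at an unadjusted p under 0.05 numbered 610; DESeq2 called 59 higher and 7 lower, and edgeR with the barcode series as a term 0 and 1. Called were 0 of 33 interferon-stimulated genes higher and 0 lower, leaving 33 (25 and 0 adjusted over the list alone), with a median of 3.04 (adjusted p = 1.88e-64, and adjusted p = 0.0275 with an estimated correlation). The count was 0 without Pten 2 d replicate 3 or Pten 2 d replicates 4 and 5, and 0 with the clusters of 1 other marker included.

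Pten/Socs3-CNTF mice were compared with controls at 2 d in the same way (n = 1 and 1). The neuropeptide genes Gal, which encodes galanin, and Crh, corticotropin-releasing hormone, were higher. So were the surface proteoglycan Sdc1, the Wnt inhibitor Sfrp1, Timp1 and Serpina3n downstream of cytokines, and the adhesion molecules Cd44 and Chl1. Antiviral genes followed, among them Rsad2, Ifit1 and the protein kinase gene Eif2ak2, with Psmb9, a subunit of the proteasome that prepares antigen. The neuronal tubulin gene Tubb3 was higher, and the retinoid receptor Rxrg lower. edgeR called 336 genes higher and 35 lower. Values were 7.64 ± 1.29 for Gal (adjusted p = 0.0103), 6.49 ± 0.75 for Sdc1 (adjusted p = 0.00396), 7.59 ± 0.99 for Timp1 (adjusted p = 0.00514) and 3.90 ± 0.57 for Psmb9 (adjusted p = 0.00779), then 7.70 ± 1.29 for Rsad2 (adjusted p = 0.01), 2.62 ± 0.56 for Tubb3 (adjusted p = 0.0276) and -2.09 ± 0.43 for Rxrg (adjusted p = 0.0248). Gal lies on chromosome 19 (3409915 to 3414544) and Psmb9 on chromosome 17 (34181987 to 34187764). For the interferon-stimulated genes, 24 of 33 were higher, 0 lower and 9 not called (32 and 0 adjusted over the list alone), and the list's median was 4.46 (adjusted p = 8.34e-54, and adjusted p = 0.0244 with an estimated correlation). Of the 23 JAK/STAT targets, 6 were called higher, 0 lower and 17 neither (11 and 0 adjusted over the list alone); the median was 2.44 (adjusted p = 5.53e-16, and adjusted p = 0.0244 with an estimated correlation). Among 30 regeneration genes 6 were higher, 0 lower and 24 not called (15 and 0 adjusted over the list alone), at a median of 1.37 (adjusted p = 4.35e-11, and adjusted p = 0.0244 with an estimated correlation). The test called 1 of 10 genes of alpha RGCs higher and 0 lower, leaving 9 (4 and 0 adjusted over the list alone), with a median of 1.46 (adjusted p = 0.000269, and adjusted p = 0.0977 with an estimated correlation). Marker lists called with the preset correlation alone were higher for T cells. Müller glia markers summed to 2651.5 CPM against 716.7, with 1 of 10 called (list adjusted p = 0.136). As each group was 1 set, no replicate could be left out. The counts were 612 genes higher and 118 lower with DESeq2 and 581 and 96 in edgeR with the barcode series as a term.

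**Figure D2:**
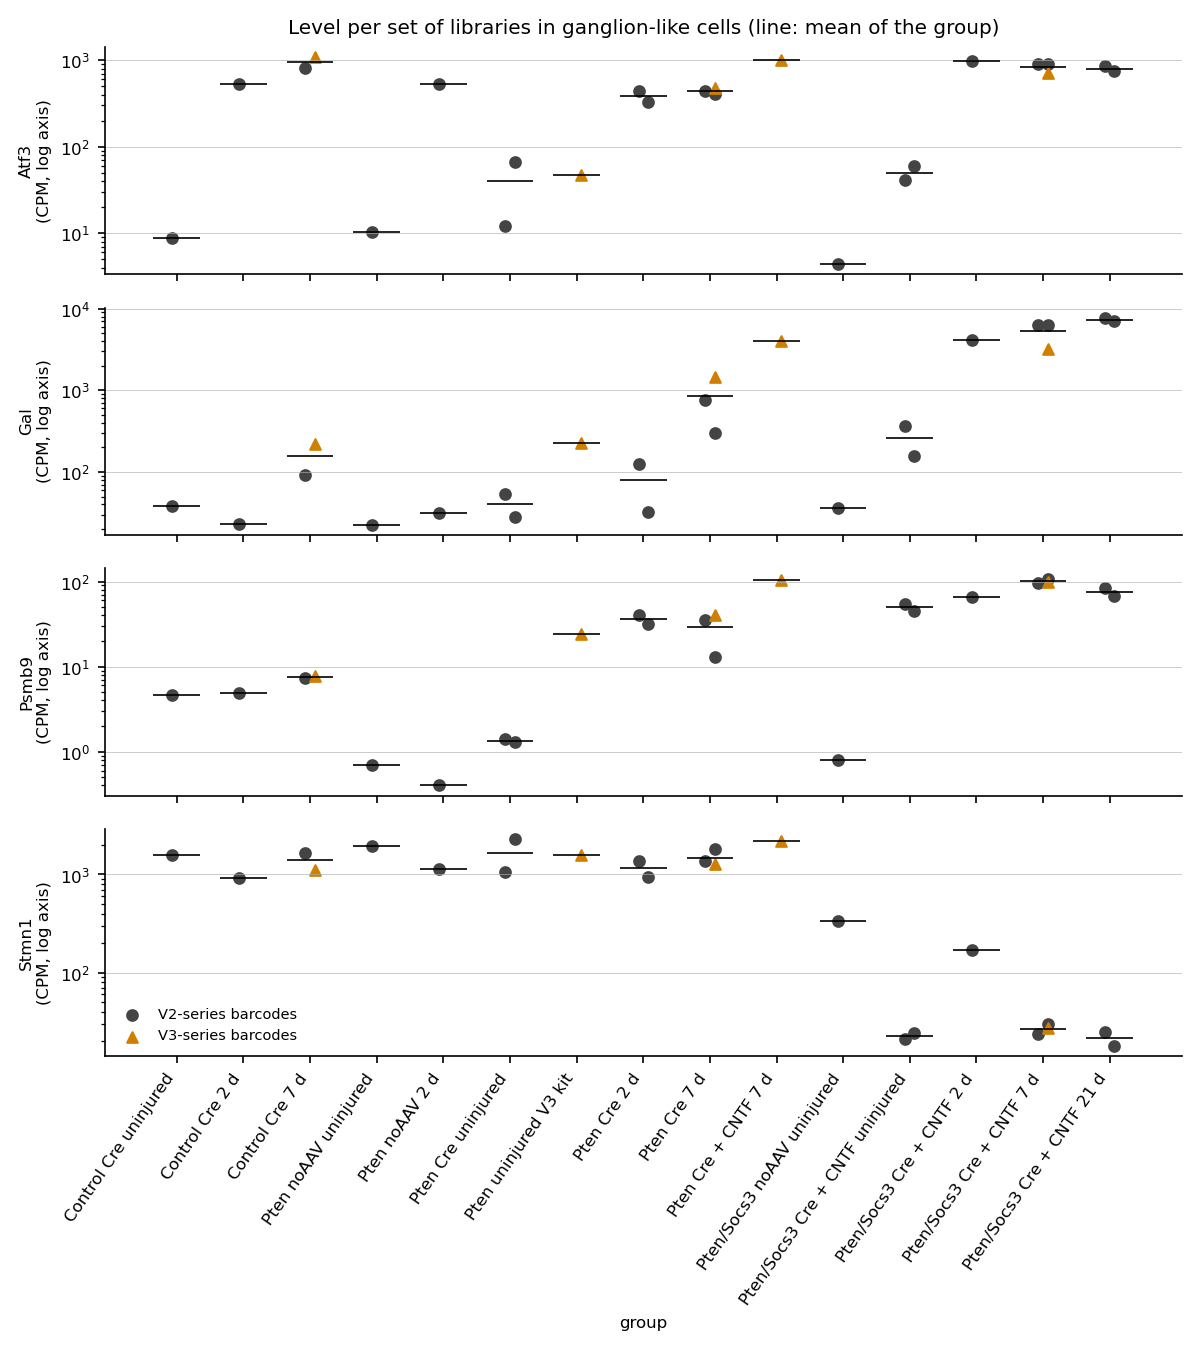
Points give the level of Atf3, Gal, Psmb9 and Stmn1 in CPM (log axis) for each set in each group, circles for V2 and triangles for V3 barcodes, with lines at group means. Psmb9 lies at 44.9 to 108.3 in Pten/Socs3-CNTF sets against 4.6 to 7.7 in control sets, and Stmn1 at 17.8 to 171.1 against 916.8 to 1669.0.

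At 7 d Pten RGCs were compared with control RGCs (n = 3 and 2). Higher in Pten mice were Chrna6, the junction protein Jam2, and Shroom2, which shapes the cell cortex. Etv1, a transcription factor of neuron types, the secreted proteins Dkk3 and Grem2 and the sugar transferases B3galt2 and Galnt16 were higher too. Lower were Tex14, Eif3j2 and Mfap1b. Stress response genes were lower as a list, and those of melanopsin RGCs, excitability and RGC identity higher, with the preset correlation. RGC types were summed and cluster shares differed, so a change per cell is not told from one in the mix of types. edgeR called 368 genes higher and 66 lower. Values were 3.06 ± 0.33 for Chrna6 (adjusted p = 0.00158), 2.12 ± 0.24 for Jam2 (adjusted p = 0.00264), 3.54 ± 0.47 for Etv1 (adjusted p = 0.00322) and 2.16 ± 0.28 for Dkk3 (adjusted p = 0.00312), and -2.03 ± 0.29 for Tex14 (adjusted p = 0.00559) and -1.16 ± 0.25 for Atf5 (adjusted p = 0.0305). The call of Atf5 (adjusted p up to 0.249) ended without Pten 7 d replicate 1, Pten 7 d replicates 3 and 4 or control 7 d replicates 1 and 2. For the stress response genes, 0 of 26 were higher, 3 lower and 23 not called (0 and 15 adjusted over the list alone), and the list's median was -1.04 (adjusted p = 3.37e-12, and adjusted p = 0.112 with an estimated correlation). Of the 10 genes of melanopsin RGCs, 5 were called higher, 0 lower and 5 neither (8 and 0 adjusted over the list alone); the median was 2.00 (adjusted p = 6.06e-10, and adjusted p = 0.112 with an estimated correlation). Among 35 excitability genes 2 were higher, 0 lower and 33 not called (15 and 0 adjusted over the list alone), at a median of 0.71 (adjusted p = 1.02e-11, and adjusted p = 0.205 with an estimated correlation). Called were 3 of 33 interferon-stimulated genes higher and 0 lower, leaving 30 (15 and 1 adjusted over the list alone), with a median of 1.19 (adjusted p = 1.79e-08, and adjusted p = 0.356 with an estimated correlation). With the preset correlation alone, markers were higher for amacrine cells, microglia and T cells and lower for rods. The count was 39 without control 7 d replicates 1 and 2, 145 without Pten 7 d replicates 3 and 4 and 160 without Pten 7 d replicate 1, and only 14 of the 48 genes named by the rule kept their call whichever library was left out. A fit of only these groups called 0, with 1981 at an unadjusted p under 0.05. DESeq2 called 871 genes higher and 327 lower, and edgeR with the barcode series as a term 1280 and 548.

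Adding CNTF to the Pten deletion was compared with controls at 7 d (n = 1 and 2). Higher were Psmb9, Serpina3n and Bcl3, which respond to interferon or to STAT3, Chl1, an adhesion molecule of growing axons, Gna14, a G protein subunit, the Wnt agonist Rspo3, and Prph, an intermediate filament of injured neurons. Gal and Fst, which encodes follistatin, were higher as well. In these libraries 37 of 83 small RNA genes expected at 20 UMIs or more had no UMI, against at most 3 in any other set, and Dis3l2, Hnrnpa1 and Tmem14c, chosen after their values were seen, stood apart from every other set compared, so calls that rest on this set alone carry that limit. Xist was at 0.0 CPM against 529.1 and 742.3 in control sets, so sex differed as well. edgeR called 664 genes higher and 159 lower. Values were 3.90 ± 0.43 for Psmb9 (adjusted p = 0.00138), 4.47 ± 0.58 for Serpina3n (adjusted p = 0.0018), 3.32 ± 0.44 for Chl1 (adjusted p = 0.0018) and 5.36 ± 0.62 for Gna14 (adjusted p = 0.00138), and 4.86 ± 0.85 for Gal (adjusted p = 0.00619), 4.98 ± 0.79 for Fst (adjusted p = 0.00353) and -1.96 ± 0.37 for Atf5 (adjusted p = 0.00976). The calls of Gal (adjusted p up to 0.0913), Fst (adjusted p up to 0.0602) and Atf5 (adjusted p up to 0.0602) ended without control 7 d replicates 1 and 2. For the interferon-stimulated genes, 23 of 33 were higher, 0 lower and 10 not called (31 and 1 adjusted over the list alone), and the list's median was 3.15 (adjusted p = 1.18e-31, and adjusted p = 0.128 with an estimated correlation). Of the 23 JAK/STAT targets, 6 were called higher, 0 lower and 17 neither (8 and 0 adjusted over the list alone); the median was 1.58 (adjusted p = 6.05e-08, and adjusted p = 0.128 with an estimated correlation). Markers of other cells, called with the preset correlation alone, were higher for amacrine cells, cones, microglia and T cells. The count was 142 without control 7 d replicates 1 and 2 and 1516 without control 7 d replicate 3, and 24 of the 60 genes named by the rule kept their call whichever library was left out. With DESeq2 the counts were 909 genes higher and 549 lower, and with the barcode series as a term in edgeR they were 948 and 273.

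The full combination, Pten/Socs3-CNTF, was compared with controls at 7 d (n = 3 and 2). Serpina3n, Timp1, Gal and Fst were far higher, with Gna14, Chl1, the growth factor receptor Ngfr and Cartpt, a neuropeptide of direction-selective RGCs. Interferon genes such as Gbp2, Isg15, Rsad2 and Psmb9 were higher, as were Tubb3, the neurofilament gene Nefl and the cholesterol genes Dhcr24 and Ldlr. Stress genes were lower, among them Ddit3 and the cystine transporter Slc7a11, and with them Hrk, the neuropeptides Npy and Ucn, the chaperone Hspa5 and Stmn1. edgeR called 1797 genes higher and 997 lower. Values were 6.08 ± 0.57 for Serpina3n (adjusted p = 0.000112), 5.23 ± 0.80 for Gal (adjusted p = 0.000796), 3.80 ± 0.39 for Psmb9 (adjusted p = 0.000114) and 1.97 ± 0.27 for Dhcr24 (adjusted p = 0.000442), then -2.23 ± 0.35 for Ddit3 (adjusted p = 0.000929), -5.17 ± 0.92 for Npy (adjusted p = 0.00203), -1.80 ± 0.36 for Hrk (adjusted p = 0.0044) and -5.68 ± 0.38 for Stmn1 (adjusted p = 6.57e-06). Among 33 interferon-stimulated genes 32 were higher, 1 lower and 0 not called (32 and 1 adjusted over the list alone), at a median of 2.94 (adjusted p = 1.98e-28, and adjusted p = 0.16 with an estimated correlation). The test called 9 of 23 JAK/STAT targets higher and 0 lower, leaving 14 (10 and 0 adjusted over the list alone), with a median of 1.43 (adjusted p = 1.26e-07, and adjusted p = 0.16 with an estimated correlation). For the stress response genes, 0 of 26 were higher, 13 lower and 13 not called (0 and 17 adjusted over the list alone), and the list's median was -1.28 (adjusted p = 3.85e-11, and adjusted p = 0.16 with an estimated correlation). Of the 24 cholesterol genes, 12 were called higher, 0 lower and 12 neither (16 and 0 adjusted over the list alone); the median was 1.09 (adjusted p = 3.01e-09, and adjusted p = 0.16 with an estimated correlation). No marker list of other cells was called; Müller glia markers summed to 1255.1 to 2203.0 CPM against 707.9 and 931.0, with 3 of 10 called (list adjusted p = 0.118). The count was 1203 without control 7 d replicates 1 and 2 and 1704 without Pten/Socs3-CNTF 7 d replicates 1 and 2, and 52 of the 78 genes named by the rule kept their call whichever library was left out. The counts were 2056 genes higher and 1401 lower with DESeq2 and 3008 and 1861 in edgeR with the barcode series as a term. Of the genes called higher before crush between the same groups, 99 were also called here where 9.3 would be by chance (Fisher's exact test, p = 2.09e-93), and of those lower 25 where 1.5 would be (p = 3.22e-27).

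**Figure D3:**
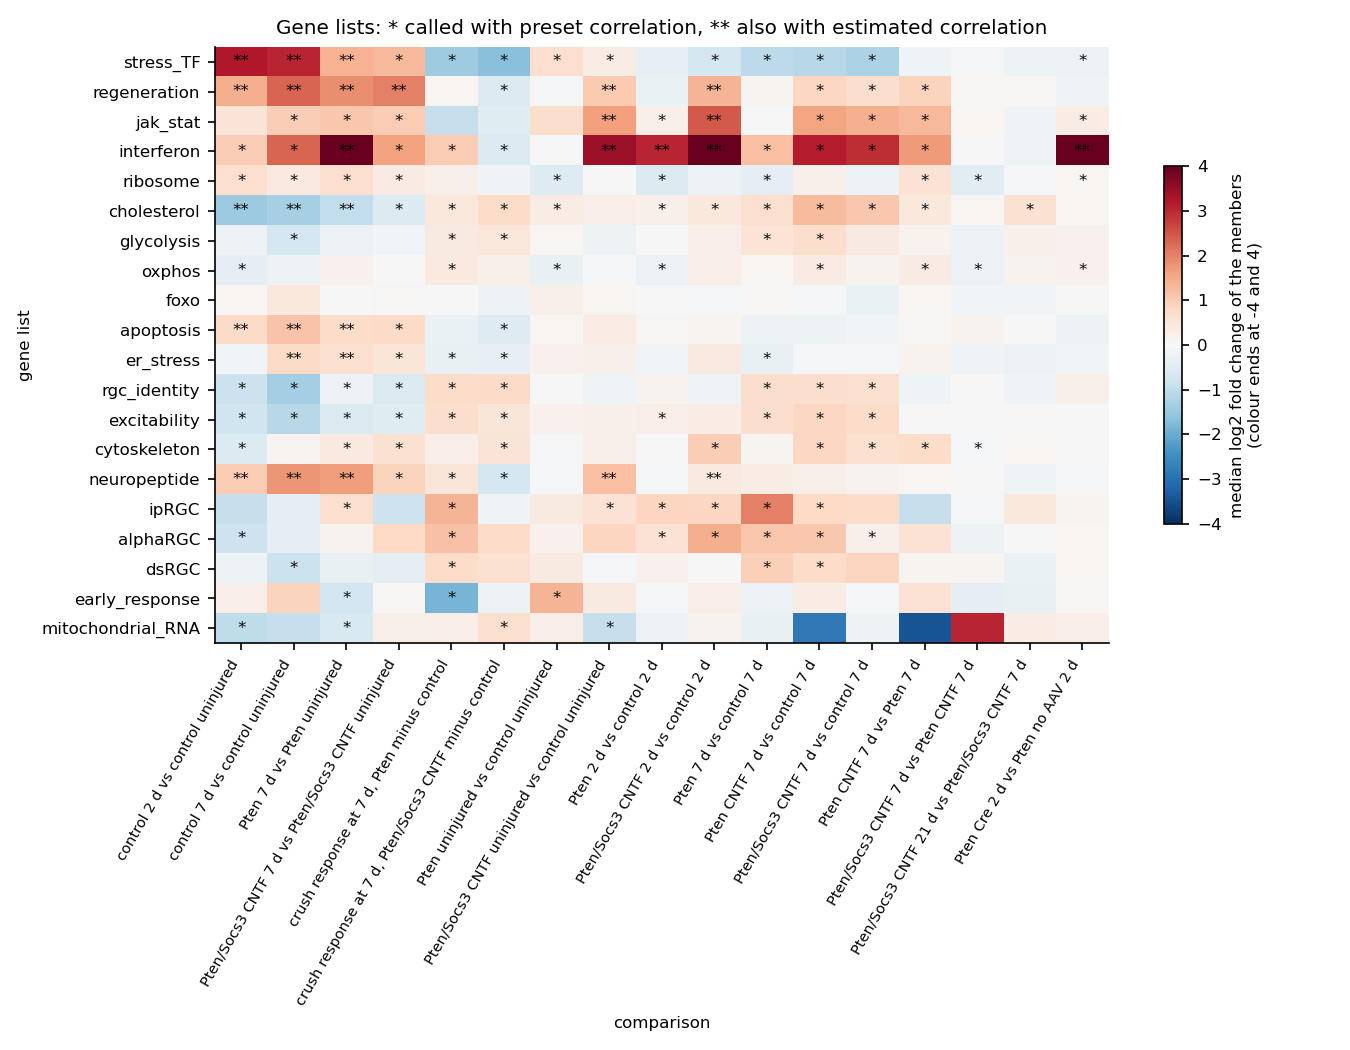
Colour gives the median log2 fold change of each gene list (down the side) in each comparison (across), ending at -4 and 4, with 1 star for lists called with the preset correlation and 2 for those also called with an estimated one. In Pten-CNTF 7 d libraries 10 of the 20 mitochondrial transcripts had no UMI, and with them at their bound the 3 medians of -2.85, -3.44 and 3.06 were -1.01, -1.45 and 1.11.

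Pten-CNTF mice were set against Pten mice at 7 d (n = 1 and 3). They differed in CNTF, its vector and sex, with Xist at 0.0 CPM against 255.0 to 948.4. Serpina3n, Timp1 and Psmb9 were higher, and with them Rasl11a, a small GTPase, Elk3, a transcription factor, Gna14 and Phf11d, a gene of the interferon response. Gpr162, an orphan receptor, and Ankrd61 were lower. Dis3l2 and Tmem14c were also called, and stood apart in the Pten-CNTF libraries from all other sets compared. edgeR called 58 genes higher and 23 lower. Values were 3.76 ± 0.50 for Serpina3n (adjusted p = 0.00856), 3.70 ± 0.55 for Timp1 (adjusted p = 0.0153), 2.06 ± 0.38 for Psmb9 (adjusted p = 0.0294) and -2.53 ± 0.37 for Gpr162 (adjusted p = 0.0153). Among 33 interferon-stimulated genes 1 was higher, 0 lower and 32 not called (26 and 0 adjusted over the list alone), at a median of 1.70 (adjusted p = 5.98e-27, and adjusted p = 0.0866 with an estimated correlation). Called were 2 of 23 JAK/STAT targets higher and 0 lower, leaving 21 (9 and 0 adjusted over the list alone), with a median of 1.30 (adjusted p = 3.95e-13, and adjusted p = 0.0838 with an estimated correlation). For the oxidative phosphorylation genes, 0 of 77 were higher, 0 lower and 77 not called (0 and 0 adjusted over the list alone), and the list's median was 0.33 (adjusted p = 0.003, and adjusted p = 0.715 with an estimated correlation). Marker lists called with the preset correlation alone were higher for bipolar cells, cones, microglia and pericytes. The count was 29 without Pten 7 d replicate 2 and 189 without Pten 7 d replicates 3 and 4, and 18 of the 24 genes named by the rule kept their call whichever library was left out. A fit of only these groups called 0, with 1566 at an unadjusted p under 0.05. The calls of Psmb9, Gna14 and Phf11d ended with the clusters of 1 other marker included. DESeq2 called 258 genes higher and 190 lower, and edgeR with the barcode series as a term 212 and 66.

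Pten/Socs3-CNTF mice were set against Pten-CNTF mice at 7 d (n = 3 and 1). Besides Socs3 they differed in line and sex, with Xist at 157.1 to 395.5 CPM against 0.0. Stmn1 was lower, and so were Dis3l2, an RNA exonuclease, and Hnrnpa1, a splicing factor, while Tmem14c, a mitochondrial membrane protein, was higher. The last 3 differed in the Pten-CNTF libraries, at 161.2, 117.3 and 10.8 CPM, from all other sets compared, and Stmn1 in the Pten/Socs3 ones. No gene list of injury, cytokine or interferon genes was called. edgeR called 27 genes higher and 33 lower. Values were -6.40 ± 0.42 for Stmn1 (adjusted p = 5.03e-06), -3.12 ± 0.25 for Dis3l2 (adjusted p = 2.2e-05), -3.56 ± 0.53 for Hnrnpa1 (adjusted p = 0.00831) and 3.34 ± 0.47 for Tmem14c (adjusted p = 0.00625). The interferon list had adjusted p = 0.804 and the JAK/STAT list adjusted p = 0.804. With the preset correlation alone, markers were lower for amacrine cells, bipolar cells, cones, microglia and pericytes. The count was 34 without Pten/Socs3-CNTF 7 d replicate 3 and 38 without Pten/Socs3-CNTF 7 d replicates 1 and 2, and 15 of the 21 genes named by the rule kept their call whichever library was left out. With DESeq2 the counts were 99 genes higher and 61 lower, and with the barcode series as a term in edgeR they were 53 and 69.

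Change from 7 d to 21 d was followed in Pten/Socs3-CNTF mice alone (n = 2 and 3). Cholesterol genes and microglia markers were higher at 21 d as lists with the preset correlation, and no gene was called. edgeR called 0 genes, with 932 at an unadjusted p under 0.05; DESeq2 called 10 higher and 7 lower, and edgeR with the barcode series as a term 0. Of the 24 cholesterol genes, 0 were called higher, 0 lower and 24 neither (8 and 0 adjusted over the list alone); the median was 0.60 (adjusted p = 1.68e-12, and adjusted p = 0.243 with an estimated correlation). Among 13 microglia markers 0 were higher, 0 lower and 13 not called (0 and 0 adjusted over the list alone), at a median of 1.22 (adjusted p = 0.000204, and adjusted p = 0.849 with an estimated correlation). The count was 1 without Pten/Socs3-CNTF 7 d replicate 3.

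In the Pten line alone, mice with AAV-Cre could be set against mice without AAV at 2 d (n = 2 and 1), the 1 comparison of mice with and without AAV within a line. Genes of the interferon response were among those called higher: Psmb9, Psmb8 and Tap1, which prepare and carry antigen peptides, Irgm2, an immunity-related GTPase, Stat1, its signal carrier, and H2-K1, which presents the peptides. edgeR called 24 genes higher and 0 lower (323 genes at an unadjusted p under 0.05), a fit of only these groups 158 and 12, and each library as its own replicate 134 and 16. Values were 6.39 ± 0.64 for Psmb9 (adjusted p = 0.00138), 5.43 ± 0.68 for Tap1 (adjusted p = 0.00933), 6.17 ± 0.80 for Psmb8 (adjusted p = 0.00933) and 2.90 ± 0.41 for Stat1 (adjusted p = 0.0168). The call of Stat1 (adjusted p up to 0.0626) ended without Pten 2 d replicates 4 and 5. The call of H2-K1 (adjusted p up to 0.0862) ended without Pten 2 d replicate 3 or Pten 2 d replicates 4 and 5. The test called 10 of 33 interferon-stimulated genes higher and 0 lower, leaving 23 (31 and 0 adjusted over the list alone), with a median of 5.10 (adjusted p = 1.68e-214, and adjusted p = 0.000268 with an estimated correlation). Markers of other cells, called with the preset correlation alone, were higher for microglia and T cells and lower for amacrine cells. The count was 5 without Pten 2 d replicate 3, 6 without Pten 2 d replicates 4 and 5 and 12 without Pten no-AAV 2 d replicate 2, and 4 of the 11 genes named by the rule kept their call whichever library was left out. Without Pten 2 d replicate 3 and Pten uninjured replicate 2, the shallowest libraries, 1 gene was called, in all cells summed 0, and with the clusters of 1 other marker included 1. The replicate block also left 1. The counts were 97 genes higher and 0 lower with DESeq2 and 27 and 0 in edgeR with the barcode series as a term.

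Markers of other retinal cells show how far RNA of those cells entered the RGC-like profiles, and FoxO targets report on the signal that Pten restrains. FoxO targets and markers of astrocytes, endothelium, fibroblasts and horizontal cells were called as lists in none of the 17 comparisons. Between controls at 7 d and uninjured, 1 of 20 FoxO targets were higher and 0 lower (adjusted p = 0.489), 0 of 6 astrocyte markers were higher and 1 lower (adjusted p = 0.83) and 0 of 7 endothelial markers were higher and 1 lower (adjusted p = 0.841). In the same comparison 0 of 3 fibroblast markers were higher and 0 lower (adjusted p = 0.488), and 0 of 4 horizontal cell markers were higher and 1 lower (adjusted p = 0.526). Rod, cone and pericyte markers were called in some comparisons with the preset correlation and in none with an estimated one. Between these control groups 1 of 10 rod markers were higher and 0 lower (adjusted p = 0.166), 0 of 7 cone markers were higher and 0 lower (adjusted p = 0.839) and 0 of 7 pericyte markers were higher and 0 lower (adjusted p = 0.991). The calls of marker lists stand with each comparison above, and none held with an estimated correlation.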

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

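The differences of responses were planned; all tests of explanations in this part, and the look at Ddx3y, were chosen after the results were seen. For the difference in response to crush at 7 d between Pten/Socs3-CNTF mice and controls, edgeR called Abi3bp (log2 3.88, adjusted p = 0.0466) and Xist (12.82, adjusted p = 0.0087). Abi3bp had few counts: 0.7 CPM in both uninjured Pten/Socs3-CNTF sets and 2.2 to 3.6 at 7 d, against 1.1 in uninjured controls and 0.3 and 0.4 at 7 d. Both calls ended when some libraries were left out, at adjusted p up to 0.333 for Abi3bp and 0.157 for Xist. The fitted Xist value rests on 0.0 and 0.2 CPM in uninjured Pten/Socs3-CNTF sets and is no measured fold. Those sets held the Y-linked Ddx3y at 35.2 and 44.6 CPM, while the sets at 7 d held Xist at 157.1 to 395.5. The Xist call thus goes with the sex of the mice and is not read as a response to crush. Ddx3y, looked at after this, had a difference of -3.17 (SE 2.12, adjusted p = 0.98 by edgeR). Uninjured, the interferon list was at 1948.3 CPM in the V3-kit Pten pair, 406.0 and 462.1 in V2 Pten sets with Cre and 652.3 in controls.

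The interferon list summed to 6.02 times its control CPM in Pten/Socs3-CNTF mice uninjured, 7.43 at 2 d and 6.38 at 7 d. The kit is argued against, as 24 members were called at 2 d where all libraries carry V2 barcodes. So is AAV-Cre as the whole cause, as Psmb9 reached at most 7.7 CPM in controls, all given it. Yet in the Pten line at 2 d the list stood at 3949.5 and 4162.7 CPM with AAV-Cre and 512.5 without. A part of AAV-Cre with the deletion thus stays open. Uninjured, V2 Pten sets with Cre (406.0 and 462.1) lay below controls, the V3-kit pair above. Microglia RNA is argued against as the whole cause by the last of 3 tests, each added after the one before was seen. Medians of the microglia markers (log2 -1.07 uninjured, -0.50 at 2 d, 0.87 at 7 d) and ratios of their sums (0.71, 0.89 and 0.87) differed in sign at 7 d. At 4.86, the highest ratio of the list to the markers in the microglia cluster (measured in 9 groups, Pten/Socs3-CNTF uninjured and at 2 d not among them), the markers present could bring at most 5.3% of the rise. Loss of Socs3 stays open. At 7 d the Pten-CNTF set (Socs3 not floxed) held the list at 8251.3 CPM. Controls held 1683.2 and 1857.3 and Pten/Socs3-CNTF sets 8963.1 to 13067.3. This points against loss as the whole cause but is 1 set, without Xist and some small RNAs. At 2 d no such group exists. Uninjured, the V3-kit pair may be one. CNTF and the second vector stay open, as 0 groups differ from another in 1 of them alone. Sex is argued against as the whole cause. The uninjured sets without Xist (0.0 and 0.2 CPM) held the list at 3920.7 and 3929.9 and the 2 d set without Ddx3y at 10110.6, against at most 1857.3 in controls.

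Stmn1 was low in libraries of the Pten/Socs3 line. The injected vectors are argued against as the whole cause by the 2 libraries that title and label give as this line without AAV, 1 of them with conflicting labels on crush: 54% and 20.2% of their cells, thinned to 5000 UMIs (shallower ones left out), had no UMI of it, against at most 4.4% in control sets, and it stood at 337.6 and 532.6 CPM, against at least 916.8. A variant that lowers the count of every cell alike stays open. If control cells were lowered to the mean of each set, at most 22.9%, 11.9% and, with both vectors at 2 d, 46.2% of cells thinned in this way would have no UMI, and 54.0%, 20.2% and 67.7% did, so 2 of these 3 sets exceeded it by over 10 percentage points and 1 did not; in the other sets 85.5 to 90.8% were expected, which left no room. Pooled animals that differ at the gene stay open, as 0 libraries tie cells to animals. No biological explanation was tested.

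Small RNA genes had no UMI in the Pten-CNTF libraries at 7 d for 37 of 83 expected at 20 or more. V3 barcodes are argued against, as at most 2 lacked a UMI in the 4 other sets that carry them. Other gene models in the count of these libraries cannot be told from a loss of these RNAs, because the tables list 312 small RNA genes for every library alike and do not name the models used. No biological explanation was tested.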

How the results depend on the processing

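Of the settings below, the barcode series as a term, V2 barcodes alone, each library as its own replicate, the fit without the shallow libraries, that with the 9 clusters set aside for 1 marker of another class and that without the highest doublet scores were chosen after the data had been seen, and the others before. Of 566 named gene results (a gene in a comparison), 274 kept direction and threshold in every setting, and 1 changed direction: Il1rapl2, at 2.03 in Pten 7 d over uninjured, was -0.02 with those clusters included. Calls ended for 1 with DESeq2, 2 with the barcode series as a term, 4 with cells of at least 1200 genes, 4 with no filter on low counts, 7 without the cells with the highest doublet scores, 9 with median-ratio size factors, 38 with the replicate block, 50 with those clusters included, 54 without the 2 shallow libraries, 56 with all cells summed, 48 of 461 with V2 barcodes alone, 18 of 70 with the V3-kit libraries and 180 of 491 with only the groups compared. Leaving out a library or set ended 517 of 4353 such calls, though where a group is 1 set this removes no replicate, and taking each library as its own replicate ended 0. Of 193 list calls, 29 held with an estimated correlation. All cells summed ended 21, those clusters 16, the barcode series as a term 13, the highest doublet scores 7, and cells of at least 1200 genes and no filter 1 each.

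The number of genes called moved beyond 1.5 times its main value as follows, and the cause was not tested unless given. With a library or set left out it ranged over 771 to 1368 for Pten 7 d over uninjured, 287 to 2039 for Pten/Socs3-CNTF 7 d over uninjured, 0 to 57 for the Pten difference of responses, 0 to 13 for the Pten/Socs3-CNTF difference of responses, 0 to 64 for Pten over control uninjured, 27 to 121 for Pten/Socs3-CNTF over control uninjured, 0 to 1 for Pten over control at 2 d, 39 to 649 for Pten over control at 7 d, 142 to 1516 for Pten-CNTF over control, 1203 to 3453 for Pten/Socs3-CNTF over control at 7 d, 29 to 189 for Pten-CNTF over Pten, 34 to 60 for Pten/Socs3-CNTF over Pten-CNTF, 0 to 1 for 21 d over 7 d and 5 to 24 for Pten with over without AAV. Control 7 d over uninjured stayed within 1.5 times; in control 2 d over uninjured and Pten/Socs3-CNTF over control at 2 d, of 1 set against 1, no replicate could be left out. DESeq2 gave 647 for control 2 d over uninjured, 1955 for Pten 7 d over uninjured, 41 for the Pten difference of responses, 173 for the Pten/Socs3-CNTF difference of responses, 18 for Pten over control uninjured, 392 for Pten/Socs3-CNTF over control uninjured, 66 for Pten over control at 2 d, 730 for Pten/Socs3-CNTF over control at 2 d, 1198 for Pten over control at 7 d, 1458 for Pten-CNTF over control, 448 for Pten-CNTF over Pten, 160 for Pten/Socs3-CNTF over Pten-CNTF, 17 for 21 d over 7 d and 97 for Pten with over without AAV. Median-ratio size factors and no filter on low counts each gave 1 for the Pten/Socs3-CNTF difference of responses. The former gave 0 for Pten over control uninjured and at 2 d. Cells of at least 1200 genes, and the fit without the cells with the highest doublet scores, each gave 1 for the Pten/Socs3-CNTF difference of responses and 2 for Pten over control uninjured. With all cells summed the counts were 5 for the Pten/Socs3-CNTF difference of responses and 0 for Pten over control uninjured, Pten over control at 2 d and Pten with over without AAV. With the clusters set aside for 1 marker included they were 0 for Pten over control uninjured and Pten over control at 2 d and 1 for Pten with over without AAV. A fit of only the libraries of the groups compared gave 757 for control 7 d over uninjured, 229 for Pten 7 d over uninjured, 1 for the Pten/Socs3-CNTF difference of responses, 0 for Pten over control uninjured, Pten over control at 7 d and Pten-CNTF over Pten, 1168 for Pten/Socs3-CNTF over control uninjured, 306 for Pten over control at 2 d, 1585 for Pten/Socs3-CNTF over control at 7 d, 9 for Pten/Socs3-CNTF over Pten-CNTF and 170 for Pten with over without AAV. The replicate block gave 1 for the Pten/Socs3-CNTF difference of responses and Pten with over without AAV, 4 for Pten over control uninjured, 0 for Pten over control at 2 d, 956 for Pten over control at 7 d, 1300 for Pten-CNTF over control and 170 for Pten-CNTF over Pten.

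With the barcode series as a term the counts were 671 for control 2 d over uninjured, 3652 for control 7 d over uninjured, 2654 for Pten 7 d over uninjured, 3197 for Pten/Socs3-CNTF 7 d over uninjured, 3 for the Pten difference of responses, 85 for the Pten/Socs3-CNTF difference of responses, 4 for Pten over control uninjured, 285 for Pten/Socs3-CNTF over control uninjured, 677 for Pten/Socs3-CNTF over control at 2 d, 1828 for Pten over control at 7 d, 4869 for Pten/Socs3-CNTF over control at 7 d, 278 for Pten-CNTF over Pten and 122 for Pten/Socs3-CNTF over Pten-CNTF. V2 barcodes alone, with 17 sets, gave 632 for control 2 d over uninjured, 1899 for Pten 7 d over uninjured, 3088 for Pten/Socs3-CNTF 7 d over uninjured, 59 for the Pten/Socs3-CNTF difference of responses, 2 for Pten over control uninjured, 332 for Pten/Socs3-CNTF over control uninjured, 830 for Pten/Socs3-CNTF over control at 2 d and 10 for Pten with over without AAV. Each library as its own replicate, the unit of the plan as first written, gave 4585 for control 2 d over uninjured, 7280 for control 7 d over uninjured, 4464 for Pten 7 d over uninjured, 4747 for Pten/Socs3-CNTF 7 d over uninjured, 1235 for the Pten difference of responses, 1453 for the Pten/Socs3-CNTF difference of responses, 505 for Pten over control uninjured, 1557 for Pten/Socs3-CNTF over control uninjured, 1278 for Pten over control at 2 d, 4967 for Pten/Socs3-CNTF over control at 2 d, 6522 for Pten over control at 7 d, 7541 for Pten-CNTF over control, 9268 for Pten/Socs3-CNTF over control at 7 d, 3422 for Pten-CNTF over Pten, 1287 for Pten/Socs3-CNTF over Pten-CNTF, 1224 for 21 d over 7 d and 150 for Pten with over without AAV. Its p values are too small if the libraries of a set share a preparation. With the V3-kit libraries in the uninjured Pten group the count was 2 for Pten over control uninjured. Without the 2 shallow Pten libraries it was 698 for Pten 7 d over uninjured, 1 for the Pten/Socs3-CNTF difference of responses and Pten with over without AAV and 0 for Pten over control uninjured and Pten over control at 2 d.

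Lists called with an estimated correlation numbered 5, 6 and 7 for control 2 d, control 7 d and Pten 7 d over uninjured. They numbered 1 for Pten/Socs3-CNTF 7 d over uninjured, Pten over control at 2 d and Pten with over without AAV. For Pten/Socs3-CNTF over control uninjured and at 2 d they numbered 4, and for the other comparisons 0. With the preset one the range was 2 to 17 of 32. From 7 d to 21 d, 4 lists were called with all cells summed and 6 with the barcode series as a term, against 2.

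The planned fit without Scrublet's doublets, 45 cells, was replaced by that without the 5% of cells with the highest doublet scores. No value could be had from only the groups compared where each had 1 set, nor from V2 barcodes for the 3 Pten-CNTF comparisons. Depth limited genes of few UMIs: those with no UMI in a group have no fold, and the Pten libraries of 7.38 and 11.84 M UMIs were the shallowest.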

Other observations

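The differences of responses were planned; the other tests in this part were chosen after the results were seen. At 7 d Chrna6 was higher and Atf5 lower in Pten mice than in controls, and Dhcr24 and Ldlr higher and Ddit3 lower in Pten/Socs3-CNTF mice, each against its change with crush in controls; both comparisons use the same control libraries at 7 d, which builds in part of this. A hypothesis is a smaller injury response with the deletion; the differences of responses, which test it, called 0 and 2 genes, and the stress list held in neither with an estimated correlation (adjusted p = 0.0798 and 0.0506). With DESeq2 the counts were 41 and 173, and edgeR recovered only 3% and 6.2% of simulated 4-fold changes in these differences, so low power could leave such genes uncalled and the hypothesis stays open.

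The genes called at 7 d were compared within each barcode series: of those called between Pten and control RGCs 434 of 434 kept their sign in V3 libraries and 432 of 432 in V2 ones, and between Pten/Socs3-CNTF and control RGCs 2791 of 2794 and 2775 of 2775. They were chosen in the same libraries, so this is no independent check. The series itself called 2672 genes higher and 1572 lower in V3 libraries.

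Other splits of the libraries, each taken as a sample, were fitted for 4 comparisons. Libraries of a set are not independent, and the sets themselves allow only 3 or 10 arrangements, too few for a share under 0.05. Between Pten/Socs3-CNTF and control libraries at 7 d the real split called 7179 genes and the highest other 1121 (1 of 84 reached the real count). For Pten against control at 7 d 2 of 35 splits did, with 1252 genes in the real one and 2946 in the one that follows the barcode series. From 7 d to 21 d 2 of 84 splits did; the real one called 1498 and the one that follows the barcode series 9340, so the samples are structured by series. With the series as a term, in the fit of all sets, which differs in form from these, the counts were 1828 and 0. At 2 d, Pten against control, 1 of 10 splits reached 5513, and the next called 0.

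The library with conflicting labels held 3366 cells and 38.72 M UMIs, 85.92% of its cells RGC-like, with Atf3 at 592.4 CPM, Stmn1 at 532.6, Xist at 978.8 and the interferon list at 483.1.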
